A study of Mus musculus with 6 samples.

How the data were processed

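Gene expression was measured on 6 Affymetrix GeneChip arrays, 3 from day 3 and 3 from day 4 of the differentiation of mouse embryonic stem (ES) cells toward paraxial mesoderm. Per the labels' protocols, total RNA was taken from cells sorted as positive for a Venus reporter of Msgn1, was amplified in 2 rounds into biotin-labelled cRNA, and 1 array was hybridised per sample. The labels name both Trizol and an RNeasy kit for the extraction and do not say which was used for which sample, so the extraction could not be tested as a batch. Per the submitters' processing notes the deposited values come from MAS5, the Affymetrix algorithm that subtracts mismatch signal and summarises the probes of each probe set. The deposited values were linear signal intensities for 45101 probe sets per array. The software version, the scaling target and the detection calls are not given in the sources used here. The arrays had been brought to a common level before deposit, as their trimmed means over the middle 96% of probe sets ran from 160.3 to 162.1, a spread of 1.10% that was within the 5% allowed in advance, so the deposited intensities were used without further scaling. Double amplification lengthens the path from RNA to signal and weighs transcripts toward their 3′ ends. MAS5 values of dim probe sets scatter widely on a log scale, so large fold changes of dim genes are imprecise.

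Probe sets were named from the array's annotation table. Of the probe sets, 34958 had 1 gene symbol, 932 had several and were left unnamed, and 9211 were not listed. Of those with 1 symbol, 34754 matched a RefSeq gene of the GRCm38.p6 assembly by Entrez identifier and 204 did not, and the match changed 0 symbols. No build is named for the array, so no coordinates are given. The 64 control probe sets were kept for quality checks only. The gene T (brachyury), which was on 2 of the gene lists, had no probe set under that name and was not analysed here.

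The computations used log2 of the deposited signal in R 4.3.3 with limma 3.58.1. Each of 18193 genes was represented by the probe set with the highest mean log2 signal over all 6 arrays. Genes whose probe set lay above the 40th percentile of all probe sets, a signal of 13.5, were tested, which left 12285 genes. A linear model with day as the only term was fitted to all 6 arrays, with moderated variances that followed the mean signal (lmFit, then eBayes with trend), 2-sided tests and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. Changes are day 4 minus day 3, on the log2 scale. Without detection calls, the filter level served as a lower limit: where the mean of 1 day lay under it, the fold is given as "at least", from the brighter day's mean of log2 signal over the mean, in log2, of the higher of the filter level and the measured signal of each dim array (a bound chosen after the data were examined).

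Gene lists, 25 in all, were fixed before the data were examined, as were the design, the genes to be named and most of the alternatives. The lists covered naive pluripotency, general and epiblast pluripotency, primitive streak and caudal epiblast, posterior presomitic mesoderm, and anterior presomitic mesoderm and somite. They also covered targets and other genes of the Notch, Wnt, FGF and BMP pathways, retinoic acid, both Hox classes, and epithelial and mesenchymal genes. Markers of cardiac and lateral plate mesoderm, endothelium and blood, neural cells, endoderm, notochord and node, germ cells and skeletal muscle formed further lists. The last were proliferation, glycolysis, stress and ribosomal proteins. Each list was tested against the other genes with camera at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 25 lists. Genes named whatever their values were Msgn1, Tbx6, Dll1, Dll3, Hes7, Lfng, Rspo3, Wnt3a, Fgf8, Cdx2, Mixl1, Eomes, Mesp2, Ripply2, Meox1, Tcf15, Foxc2, Aldh1a2, Pax3, Pou5f1, Nanog and Sox2. The 10 largest rises and 10 largest falls by fitted log2 change were taken among genes past the threshold whose 3 values of each day did not overlap and whose brighter day exceeded the median probe set, leaving out clone names. Up to 4 members of each list with the smallest p were added.

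The alternatives were an offset of 4.14 (the 20th percentile of all values) before log2, quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, the mean over a gene's probe sets, leaving out probe sets with the suffixes _x_at, _s_at and _a_at, every probe set tested on its own, eBayes without trend, array quality weights, a replicate block, an adjusted threshold of 0.10, camera with an estimated correlation, fry, and leaving out each array in turn. Counts per list without day 4 replicate 1, and tests of each end of the Gapdh and Actb controls on its own, were added after the control signals had been seen. The model was tested on simulated arrays with the means and spreads of the 12285 genes. Of genes changed 1.5-fold, 40.3% were recovered, of those changed 2-fold 67.2%, and of those changed 4-fold 86.4%, with 5 false calls among 134 and 0 calls in arrays with no change. Of 99 unshifted simulated lists, 1 had a camera p under 0.05. The simulated genes varied independently of each other, while the estimated correlation within the real lists reached 0.327. Far fewer genes were changed than in the data, and no simulated array stood apart. These rates need not hold for the real arrays, and the simulation cannot show that the preset correlation suits the real lists. The number of arrays limits the precision, and the labels call the replicates biological without saying what was repeated.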

Results

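Mouse E14 ES cells carrying an Msgn1-Venus reporter were grown as a monolayer with 0.5% DMSO, 10 ng/mL R-spondin3, a potentiator of Wnt signalling, and 200 ng/mL Noggin, a BMP antagonist. Venus-positive cells were sorted after 3 or 4 days, and 3 biological replicates of each day were profiled. Msgn1 encodes a transcription factor of the presomitic mesoderm, the tissue that forms the somites, so the arrays compare cells of 1 reporter gate at 2 successive days. Pearson correlations of log2 signal over all probe sets were 0.941 to 0.946 between day 3 replicates, 0.933 to 0.948 between day 4 replicates and 0.924 to 0.939 between days. No pair of arrays held the same values. By median absolute log2 difference, the closest pairs were day 3 replicates 2 and 3 (0.1270) and day 4 replicates 2 and 3 (0.1275).

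Day 4 replicate 1 stood apart in its control probe sets. Its ratio of 3′ to 5′ signal was 14.0 for Gapdh and 6.71 for Actb, against 2.43 to 3.19 and 2.77 to 3.84 on the other 5 arrays. The 5′ Gapdh signal was 484 on this array, 2185 and 2648 on the other day 4 arrays and 2750 to 3108 on the day 3 arrays. The 5′ Actb signal was 1383 on this array, 2280 and 2540 on the other day 4 arrays and 2807 to 3726 on the day 3 arrays. The 5′ signals of both controls were thus lower on all 3 day 4 arrays than on any day 3 array, as was the 3′ Gapdh signal (6791 to 6978 against 7258 to 7547), each with an exact 2-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow. The ratios of the days overlapped (exact permutation p = 0.3 for Gapdh and 0.2 for Actb), as did the 3′ Actb signals (exact permutation p = 0.3). Of the spike-in controls, bioD was higher on all day 4 arrays (exact permutation p = 0.1), and bioB, bioC and cre were not separated (exact permutation p = 0.6, 0.4 and 0.2). The median within-day SD over the genes tested was 0.138 on the log2 scale at day 3 and 0.184 at day 4. For day 4 without replicate 1 it was 0.090, a value over 2 arrays that does not compare directly with those over 3. By median absolute log2 difference, replicates 2 and 3 were about as close at day 3 (0.1270) as at day 4 (0.1275). As day 4 replicate 1 stood apart, counts for each gene group are also given without it.

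**Figure D1:**
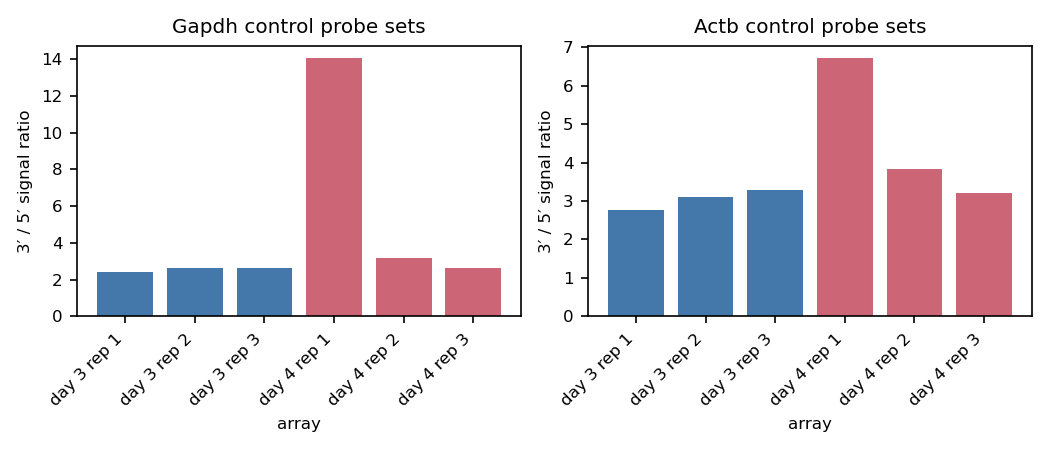
Ratio of 3′ to 5′ signal (linear axis) of the Gapdh and Actb control probe sets on each array, with day 3 in blue and day 4 in red. Day 4 replicate 1 has ratios of 14.0 and 6.71, above those of the other 5 arrays.

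Signals of many epiblast, primitive streak and epithelial genes were lower at day 4 than at day 3. Signals of many anterior presomitic and BMP pathway genes were higher. A change within the cells and a change in the mix of cells sorted were not told apart. Of 12285 genes tested, 2729 changed, 1411 of them higher and 1318 lower at day 4 (limma, adjusted p under 0.05). A change of at least 2-fold was seen in 230 of the higher and 266 of the lower genes. The first principal component held 50.7% of the variance and separated the days, with all day 3 arrays between -29.0 and -26.6 and all day 4 arrays between 25.0 and 33.7. The count was 1582 without day 3 replicate 3, 1808 without day 3 replicate 2 and 3530 without day 4 replicate 1. Of 1469 changed genes with another tested probe set, 1054 had all of these in the same direction, and 39 had a probe set called in the opposite direction.

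Msgn1 itself, the gene whose reporter defined the gate, fell from a signal of 74.6 ± 15.0 at day 3 to 33.2 ± 7.06 at day 4 (mean ± SD, n = 3 arrays per day, as for all signals that follow), a log2 change of -1.17 ± 0.24 (SE, as for all changes that follow; adjusted p = 0.00723). Among the other genes of the posterior presomitic mesoderm, Rspo3, which encodes the Wnt potentiator that was also in the medium, rose by 1.08 ± 0.08 from 1275 ± 39.3 to 2695 ± 257 (adjusted p = 5.09e-05). Dkk1, a secreted Wnt inhibitor, fell by 1.45 ± 0.14, and Dusp4, an ERK phosphatase, fell by 0.87 ± 0.08 (adjusted p = 0.000152 and 0.00012). Cdh11, a mesenchymal cadherin, fell by 0.88 ± 0.11 (adjusted p = 0.000626, and 0.0558 with the mean over its probe sets). Several core genes of this tissue did not pass. Tbx6, a transcription factor of the presomitic mesoderm, was at 132 ± 6.99 and 124 ± 29.5, and the Notch ligand Dll1 at 561 ± 35.4 and 613 ± 116. Without day 4 replicate 3 the Tbx6 change was 0.03, and without day 4 replicate 1 that of Dll1 was -0.04. The Notch ligand Dll3 changed by 0.22 ± 0.09 (adjusted p = 0.125), the clock gene Hes7 by 0.40 ± 0.24 (adjusted p = 0.271, and a change of 0.24 without day 3 replicate 2 and 0.60 without day 3 replicate 3) and the glycosyltransferase Lfng by 1.17 ± 0.78 (adjusted p = 0.314), or 0.082 without day 3 replicate 1 and up to 1.89 without another array (day 3 replicate 3). Over the list, 3 of 18 tested members were higher and 4 lower at day 4 (3 and 5 adjusted over the list alone, and 3 and 5 without day 4 replicate 1). The list did not shift as a whole (camera adjusted p = 0.869), and its median change of 0.11 and mean change of -0.14 differed in sign.

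**Figure D2:**
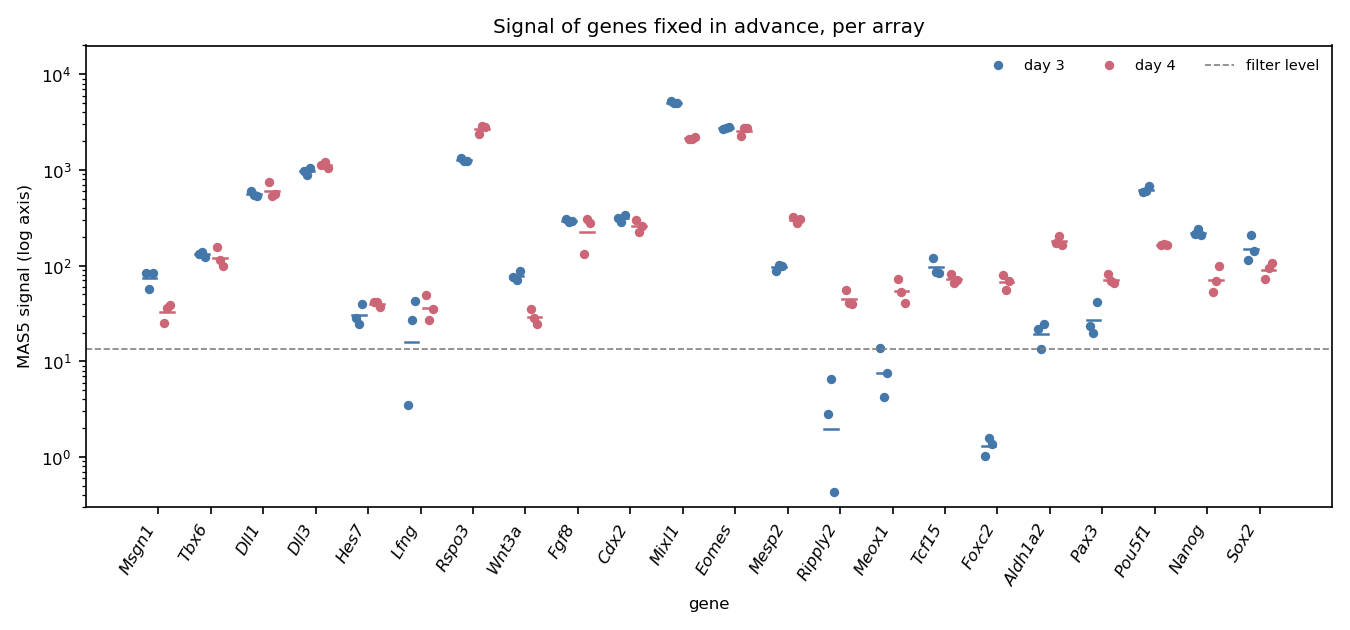
MAS5 signal (log axis) of the genes fixed in advance on each of the 3 arrays of day 3 (blue) and day 4 (red), with bars at the geometric mean and the filter level of 13.5 as a dashed line. Mesp2, Meox1, Foxc2 and Aldh1a2 are higher on all day 4 arrays, and Pou5f1, Mixl1 and Wnt3a are lower.

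Genes of the anterior presomitic mesoderm and somite rose together. Of 14 tested members, 9 were higher and 0 lower at day 4, with the same counts adjusted over the list alone and without day 4 replicate 1, and the list shifted upward (median change 0.98, camera adjusted p = 6.78e-06, and 0.0346 with an estimated correlation). Aldh1a2, which makes retinoic acid, rose from 19.9 ± 5.73 to 181 ± 22.1, a change of 3.23 ± 0.23 (adjusted p = 3.64e-05). Mesp2, the transcription factor that sets segment boundaries, rose by 1.65 ± 0.12 from 96.3 ± 8.08 to 301 ± 22.4 (adjusted p = 3.72e-05). The forkhead gene Foxc1 rose by 1.59 ± 0.16, and Pax3, a gene of the early somite, by 1.41 ± 0.28 (adjusted p = 0.000194 and 0.00715). Pcdh8, a protocadherin of the segmenting mesoderm, rose from 288 ± 32.9 to 579 ± 107 (adjusted p = 0.00141). Meox1, a homeobox gene of the somite, rose at least 3.96-fold to 55.3 ± 16.0 (adjusted p = 0.00237). Foxc2 and Ripply2 lay under the filter. Their signals were 1.33 ± 0.28 and 3.25 ± 3.08 at day 3 and 68.6 ± 12.7 and 45.4 ± 8.99 at day 4, and both passed when no filter was applied (adjusted p = 0.000115 and 0.0106). Tcf15, a regulator of somite epithelium, did not pass, with 97.1 ± 20.5 at day 3 and 72.9 ± 8.64 at day 4 (adjusted p = 0.142). Another 10 of the 12 members under the filter, among them Pax1, Pax9, Meox2, Tbx18 and Uncx, were not tested.

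The retinoic acid list did not shift (camera adjusted p = 0.869). Of 8 tested members, 2 were higher and 0 lower (2 and 1 adjusted over the list alone, and 2 and 0 without day 4 replicate 1). They were Aldh1a2 and Crabp1, a cytosolic retinoic acid carrier, which rose by 0.71 ± 0.16 (adjusted p = 0.011). Crabp2 and the retinol dehydrogenase Rdh10 did not pass (changes of -0.40 ± 0.14 and -0.30 ± 0.14, adjusted p = 0.065 and 0.149), although Crabp2 passed with quantile normalization (adjusted p = 0.0428) and with array weights (adjusted p = 0.041), and without day 4 replicate 3 the change of Rdh10 was -0.17. The median change was -0.14 and the mean 0.34.

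Genes of general and epiblast pluripotency fell. Of 21 tested members, 15 were lower and 0 higher, also adjusted over the list alone, and 14 and 0 without day 4 replicate 1 (median change -0.66, camera adjusted p = 3.59e-10, and 0.0314 with an estimated correlation). L1td1, an RNA-binding protein of ES cells, fell by 3.36 ± 0.12 from 825 ± 61.1 to 80.4 ± 9.21 (adjusted p = 1.89e-06). Pou5f1, which encodes Oct4, fell by 1.91 ± 0.10 from 622 ± 44.3 to 165 ± 2.53 (adjusted p = 6.05e-06). Fgf5, a marker of the primed epiblast, fell by 2.20 ± 0.11, and the Nodal antagonists Lefty1 and Lefty2 by 2.69 ± 0.17 and 1.75 ± 0.08 (adjusted p = 5.64e-06, 1.88e-05 and 3.84e-06). Sox2 fell by 0.75 ± 0.22 from 155 ± 47.5 to 90.5 ± 17.0 (adjusted p = 0.0389), a call that was lost in 4 of the 6 fits that left out an array (without day 3 replicate 2 or 3 or day 4 replicate 1 or 2, adjusted p up to 0.129). Some members stayed abundant: Tdgf1, the Nodal coreceptor, was at 6279 ± 61.8 and 5310 ± 63.2, a fall of 0.24 ± 0.05 (adjusted p = 0.00661).

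The naive pluripotency list did not shift (camera adjusted p = 0.422). Of 17 tested members, 3 were higher and 5 lower at day 4 (3 and 6 adjusted over the list alone, and 3 and 5 without day 4 replicate 1). Nanog fell by 1.63 ± 0.21 from 221 ± 19.7 to 73.6 ± 23.0 (adjusted p = 0.000738), and Fbxo15 fell by 1.58 ± 0.23 (adjusted p = 0.00135). Socs3, a feedback inhibitor of cytokine signalling, rose by 1.88 ± 0.18 from 104 ± 17.4 to 385 ± 86.1 (adjusted p = 0.000157), and Prdm14 rose at least 2.86-fold to 38.6 ± 3.88 (adjusted p = 0.0016).

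Genes of the primitive streak and caudal epiblast fell in 13 of 20 tested members and rose in 1, also adjusted over the list alone, and in 14 and 2 without day 4 replicate 1 (median change -0.66, camera adjusted p = 2.52e-07, and 0.0314 with an estimated correlation). Nkx1-2, a homeobox gene of the caudal epiblast, fell by 2.77 ± 0.11 from 408 ± 16.0 to 59.8 ± 0.86 (adjusted p = 1.96e-06). Mixl1, a homeobox gene of the streak, fell by 1.24 ± 0.06 from 5065 ± 123 to 2151 ± 34.7 (adjusted p = 3.84e-06). Fst, a secreted activin inhibitor, fell by 1.60 ± 0.09, and Gsc, an organizer homeobox gene, by 1.67 ± 0.15 (adjusted p = 9.26e-06 and 0.00012). Wnt3a fell by 1.43 ± 0.20 from 78.6 ± 8.95 to 29.4 ± 5.42 (adjusted p = 0.00125). Eomes, a T-box gene of the streak, did not pass, with 2741 ± 50.2 and 2583 ± 268 (adjusted p = 0.463). Cdx2 was at 316 ± 27.0 and 260 ± 37.6 (adjusted p = 0.142, 0.022 without day 4 replicate 1 and 0.0114 with array weights), and Fgf8 at 294 ± 14.2 and 240 ± 93.9 (change -0.39, adjusted p = 0.336, and a change of -0.0042 without day 4 replicate 1).

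Epithelial genes fell as a group, in 12 of 18 tested members with 0 higher (13 and 0 adjusted over the list alone, and 12 and 1 without day 4 replicate 1; median change -1.18, camera adjusted p = 3.59e-10, and 0.0314 with an estimated correlation). Ap1m2, an epithelial clathrin adaptor, fell by 2.24 ± 0.13, and Esrp1, an epithelial splicing regulator, by 1.85 ± 0.13 (adjusted p = 9.26e-06 and 2.57e-05). The keratin Krt8 fell by 1.23 ± 0.08 from 5254 ± 273 to 2247 ± 222, and the adhesion gene Epcam by 1.22 ± 0.08 from 973 ± 18.8 to 418 ± 20.6 (adjusted p = 1.94e-05 and 2.66e-05). The mesenchymal list split, with 5 of 21 tested members higher and 6 lower (the same adjusted over the list alone, and 5 and 7 without day 4 replicate 1), and did not shift (camera adjusted p = 0.869, median change 0.03, mean change -0.09). Fbn2, a fibrillin, rose by 1.29 ± 0.12 and Twist1 by 1.04 ± 0.16 (adjusted p = 0.000176 and 0.00172), while Cdh11 fell. Sparc, a matrix protein, rose by 0.59 ± 0.09 (adjusted p = 0.00174), but its other 2 probe sets went the other way without passing, and the mean over its probe sets was -0.19.

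Genes of the BMP list, which holds targets, ligands and antagonists, were higher as a group at day 4. Noggin was in the medium on both days, and BMP activity was not measured. Of 15 tested members of the BMP list, 10 were higher and 1 lower, also adjusted over the list alone, and 11 and 1 without day 4 replicate 1 (median change 0.73, camera adjusted p = 2.24e-06, and 0.0346 with an estimated correlation). Id2 rose by 2.05 ± 0.12 from 85.9 ± 7.69 to 356 ± 11.2 and Id3 by 1.63 ± 0.13 from 299 ± 50.3 to 921 ± 20.9 (adjusted p = 9.26e-06 and 5.09e-05). Both encode inhibitors of basic helix-loop-helix factors, and with the mean over its probe sets Id2 did not pass (adjusted p = 0.0529). Smad6, an inhibitor of BMP signalling, rose by 1.48 ± 0.15, and the ligand Bmp7 by 0.85 ± 0.11 (adjusted p = 0.000219 and 0.00084).

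Wnt target genes were lower in 7 of 15 tested members and higher in 2 (8 and 2 adjusted over the list alone, and 7 and 1 without day 4 replicate 1; median change -0.29, camera adjusted p = 0.046). The shift was lost with an estimated correlation (adjusted p = 0.304) and without day 3 replicate 2, day 3 replicate 3, day 4 replicate 2 or day 4 replicate 3 (adjusted p = 0.0792, 0.0777, 0.0572 and 0.0515). Ccnd1, which encodes cyclin D1, fell by 1.56 ± 0.10 from 696 ± 22.8 to 237 ± 23.7, and Sp5, a transcription factor induced by Wnt, by 1.09 ± 0.12 (adjusted p = 2.17e-05 and 0.000302). Dkk1 and Wnt3a, given above, were the other 2 with the smallest p. The FGF and ERK list did not shift (camera adjusted p = 0.236), with 4 of 17 tested members higher and 6 lower (4 and 7 adjusted over the list alone, and 4 and 8 without day 4 replicate 1). The phosphatase Dusp6 fell by 1.23 ± 0.12 from 1375 ± 196 to 585 ± 61.2, and Spry4, a feedback inhibitor, by 1.12 ± 0.14 (adjusted p = 0.000193 and 0.000558). Egr1, an immediate early transcription factor, rose by 0.90 ± 0.09 from 978 ± 114 to 1812 ± 13.1 (adjusted p = 0.000208).

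Of 16 tested members of the Notch list, 4 were higher and 0 lower, also adjusted over the list alone, and 4 and 1 without day 4 replicate 1. The list did not pass as a whole (camera adjusted p = 0.095). Hey1, a Notch target, rose by 1.03 ± 0.16, and the receptor Notch3 by 0.75 ± 0.10 (adjusted p = 0.00191 and 0.000832). Notch1 and the feedback inhibitor Nrarp rose by 0.36 ± 0.10 and 0.37 ± 0.10 (adjusted p = 0.0268 and 0.0284). These calls were lost in 4 fits that left out an array for Notch1 (each day 3 replicate or day 4 replicate 3, adjusted p up to 0.107) and in 3 for Nrarp (day 3 replicate 2 or 3 or day 4 replicate 2, up to 0.112), and the other probe set of Nrarp went the other way without passing.

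Hox genes that changed were all higher at day 4. Of the anterior groups 1 to 4, 2 of 9 tested members rose and 0 fell, also adjusted over the list alone and without day 4 replicate 1 (median change 0.48, camera adjusted p = 0.0275). With an estimated correlation the shift was lost (adjusted p = 0.308). Hoxb3 rose by 1.56 ± 0.17 from 54.5 ± 11.5 to 159 ± 8.28 and Hoxb2 by 1.22 ± 0.16 (adjusted p = 0.000331 and 0.000738). Hoxb4 and Hoxc4 did not pass (changes of 0.91 ± 0.34 and 0.88 ± 0.39, adjusted p = 0.0809 and 0.138). Hoxb4 passed without day 3 replicate 2 (1.24, adjusted p = 0.0355) and was at 0.52 without day 3 replicate 1, and Hoxc4 passed with array weights (1.09, adjusted p = 0.0407) and was at 0.38 without day 3 replicate 3. Of groups 5 to 13, 4 of 13 tested members rose and 0 fell, also adjusted over the list alone and without day 4 replicate 1, and the list did not shift (camera adjusted p = 0.227, median change -0.10, mean change 0.22). Hoxa9 rose by 1.09 ± 0.15 from 121 ± 21.9 to 254 ± 24.5, with its other probe set going the other way without passing (adjusted p = 0.00128, and 0.813 with the mean of both). Hoxd9 rose by 0.59 ± 0.10 and Hoxd8 by 0.85 ± 0.18 (adjusted p = 0.0032 and 0.00868). Hoxc8 rose by 1.02 ± 0.27 (adjusted p = 0.023), a call lost without day 3 replicate 2 or 3 or day 4 replicate 3 (adjusted p up to 0.0742).

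Markers of other lineages that the gate could hold moved unevenly. The cardiac and lateral plate list was higher in 6 of 16 tested members and lower in 1 (7 and 1 adjusted over the list alone and also without day 4 replicate 1; median change 0.58, camera adjusted p = 0.0352). The shift was lost with an estimated correlation (adjusted p = 0.221) and without day 4 replicate 2 (adjusted p = 0.0535). That estimate was -0.036, below the preset 0.01, so a higher correlation between members is not what raised the adjusted p. Tbx20, a cardiac T-box gene, rose by 1.71 ± 0.18 from 150 ± 35.8 to 487 ± 76.9, and Isl1, a gene of the second heart field, by 1.16 ± 0.10 from 232 ± 20.1 to 517 ± 7.52 (adjusted p = 0.000289 and 0.000107). Tnni1, a slow troponin, rose at least 3.47-fold to 48.5 ± 15.3 (adjusted p = 0.000644). Gata6 fell by 0.97 ± 0.12 (adjusted p = 0.000535, and 0.149 with the mean over its probe sets). The endothelium and blood list did not shift (camera adjusted p = 0.407). It had 1 of 10 tested members higher and 2 lower, also adjusted over the list alone, and 1 and 3 without day 4 replicate 1. Kdr, the VEGF receptor of vascular progenitors, rose by 1.19 ± 0.14 and the vascular factor Etv2 fell by 0.94 ± 0.15 (adjusted p = 0.000522 and 0.00196). Lmo2 fell by 0.54 ± 0.12 (adjusted p = 0.0107), a call lost without day 3 replicate 2 (adjusted p = 0.053), and Cdh5 was at 19.3 ± 0.88 and 11.8 ± 4.30 (adjusted p = 0.192).

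The neural list did not shift (camera adjusted p = 0.617), with 2 of 12 tested members higher and 3 lower, also adjusted over the list alone, and 1 and 2 without day 4 replicate 1. Irx3 rose by 1.45 ± 0.20 and Fabp7, a radial glia lipid carrier, fell by 1.33 ± 0.21 (adjusted p = 0.00101 and 0.00233). Nes fell by 0.76 ± 0.20 and Msi1 rose by 0.53 ± 0.15 (adjusted p = 0.0255 and 0.0356), and each call was lost in 5 of the 6 fits that left out an array, all except that without day 4 replicate 1 for Nes and day 4 replicate 3 for Msi1 (adjusted p up to 0.0914 and 0.109). The endoderm list did not shift (camera adjusted p = 0.869, median change 0.04, mean change -0.15), with 2 of 15 tested members higher and 4 lower, also adjusted over the list alone, and 5 and 4 without day 4 replicate 1. Sox17 fell by 1.93 ± 0.41 from 72.2 ± 22.9 to 20.2 ± 10.8 (adjusted p = 0.00956, and 0.051 without day 3 replicate 1). The forkhead gene Foxa2 fell by 1.02 ± 0.21, and Lama1, a laminin chain, rose by 0.92 ± 0.12 (adjusted p = 0.00747 and 0.00076).

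The notochord and node list was lower in 3 of 5 tested members, also adjusted over the list alone and without day 4 replicate 1 (median change -0.93, camera adjusted p = 0.0384). The shift was lost with an estimated correlation (adjusted p = 0.304) and without day 3 replicate 1 (adjusted p = 0.077). The 3 were Nodal, which fell by 1.43 ± 0.11 from 1289 ± 67.6 to 479 ± 64.2, the carbonic anhydrase gene Car3, which fell by 0.93 ± 0.08, and Foxa2 (adjusted p = 4.3e-05 and 7.91e-05 for the first and second). Nodal is also expressed in the epiblast. Sox9 did not pass (adjusted p = 0.203). The germ cell list did not shift (camera adjusted p = 0.113). It had 0 of 10 tested members higher and 2 lower, also adjusted over the list alone and without day 4 replicate 1. Ddx4 fell by 0.76 ± 0.19 (adjusted p = 0.0178, and up to 0.0752 without day 3 replicate 2 or 3), and Tex19.1 by 0.65 ± 0.20 (adjusted p = 0.0443, lost in all fits that left out an array except that without day 4 replicate 1, up to 0.157). Tfap2c and Prdm1 did not pass (adjusted p = 0.102 and 0.341). The skeletal muscle list did not shift (camera adjusted p = 0.869, median change -0.14, mean change 0.05), with 1 of 7 tested members higher and 1 lower, also adjusted over the list alone and without day 4 replicate 1. These were Des, which rose by 0.99 ± 0.31, and Actc1, which fell by 0.32 ± 0.10 (adjusted p = 0.0494 and 0.0469). The other probe set of Des went the other way without passing, and the mean over its probe sets was 0.40 (limma adjusted p = 0.461). Both calls were lost when single arrays were left out, for Des without day 3 replicate 1 or 3 or day 4 replicate 2 or 3 and for Actc1 without any array except day 4 replicate 1 (adjusted p up to 0.158 and 0.125). Myod1 and Tnnc1 did not pass (adjusted p = 0.538 and 0.547).

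The proliferation list did not shift (camera adjusted p = 0.848, median change -0.08), with 3 of 23 tested members higher and 2 lower (3 and 3 adjusted over the list alone, and 4 and 4 without day 4 replicate 1). Mki67 rose by 0.35 ± 0.07 from 2675 ± 29.3 to 3427 ± 301 and the cyclin gene Ccne1 fell by 0.63 ± 0.11 from 2182 ± 339 to 1401 ± 113 (adjusted p = 0.00772 and 0.00389), and Mki67 did not pass without the variance trend (adjusted p = 0.0568). Tyms rose by 0.97 ± 0.21 (adjusted p = 0.0102), with its other probe set going the other way without passing, and Bub1 by 0.28 ± 0.07 (adjusted p = 0.0157, and up to 0.074 without day 3 replicate 2 or 3 or day 4 replicate 2). The glycolysis list was lower in 7 of 19 tested members and higher in 3 (8 and 3 adjusted over the list alone and also without day 4 replicate 1; median change -0.21, camera adjusted p = 0.0199). With an estimated correlation the shift was lost (adjusted p = 0.377). The glucose transporter gene Slc2a1 fell by 0.77 ± 0.07 from 3344 ± 173 to 1960 ± 77.9, and the hexokinase gene Hk2 by 1.11 ± 0.15 from 1056 ± 102 to 494 ± 101 (adjusted p = 0.000105 and 0.000832). Aldoc, an aldolase, rose by 1.02 ± 0.13 (adjusted p = 0.000715, and 0.0815 with the mean over its probe sets). Pfkl fell by 0.47 ± 0.08 (limma adjusted p = 0.0025) on a probe set with the suffix _a_at. It rose by 0.49 (limma adjusted p = 0.0422) when probe sets with the suffixes _x_at, _s_at and _a_at were left out.

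The immediate early and stress list did not pass as a whole (camera adjusted p = 0.113), with 3 of 22 tested members higher and 8 lower (5 and 10 adjusted over the list alone, and 4 and 9 without day 4 replicate 1). The heat shock gene Hspa1b fell by 1.35 ± 0.12 from 390 ± 46.7 to 153 ± 11.4, the stress factor gene Atf3 by 1.40 ± 0.16, and the chaperone gene Hsph1 by 0.47 ± 0.06 (adjusted p = 0.000137, 0.00037 and 0.000683). Egr1, given above, was the other of the 4 members with the smallest p and rose by 0.90 ± 0.09 (limma adjusted p = 0.000208). Hspa1a, a near-identical copy of Hspa1b, has a probe set of its own and is counted apart, also among the 8 lower. Whether the probe sets tell the copies apart was not tested. Ribosomal protein genes did not shift (camera adjusted p = 0.236, median change 0.03), with 2 of 18 tested members higher and 0 lower, also adjusted over the list alone and without day 4 replicate 1. These were Rps15 and Rps19, with rises of 0.23 ± 0.06 and 0.30 ± 0.08 (adjusted p = 0.0192 and 0.0285). Both calls were lost without day 3 replicate 2 or 3, and also without day 4 replicate 2 for Rps15 and day 3 replicate 1 for Rps19 (adjusted p up to 0.0865 and 0.112). Rpl11 and Rps24 did not pass (adjusted p = 0.0761 and 0.0776), although Rpl11 passed without day 3 replicate 1 (adjusted p = 0.0495) and with array weights (adjusted p = 0.0226).

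**Figure D3:**
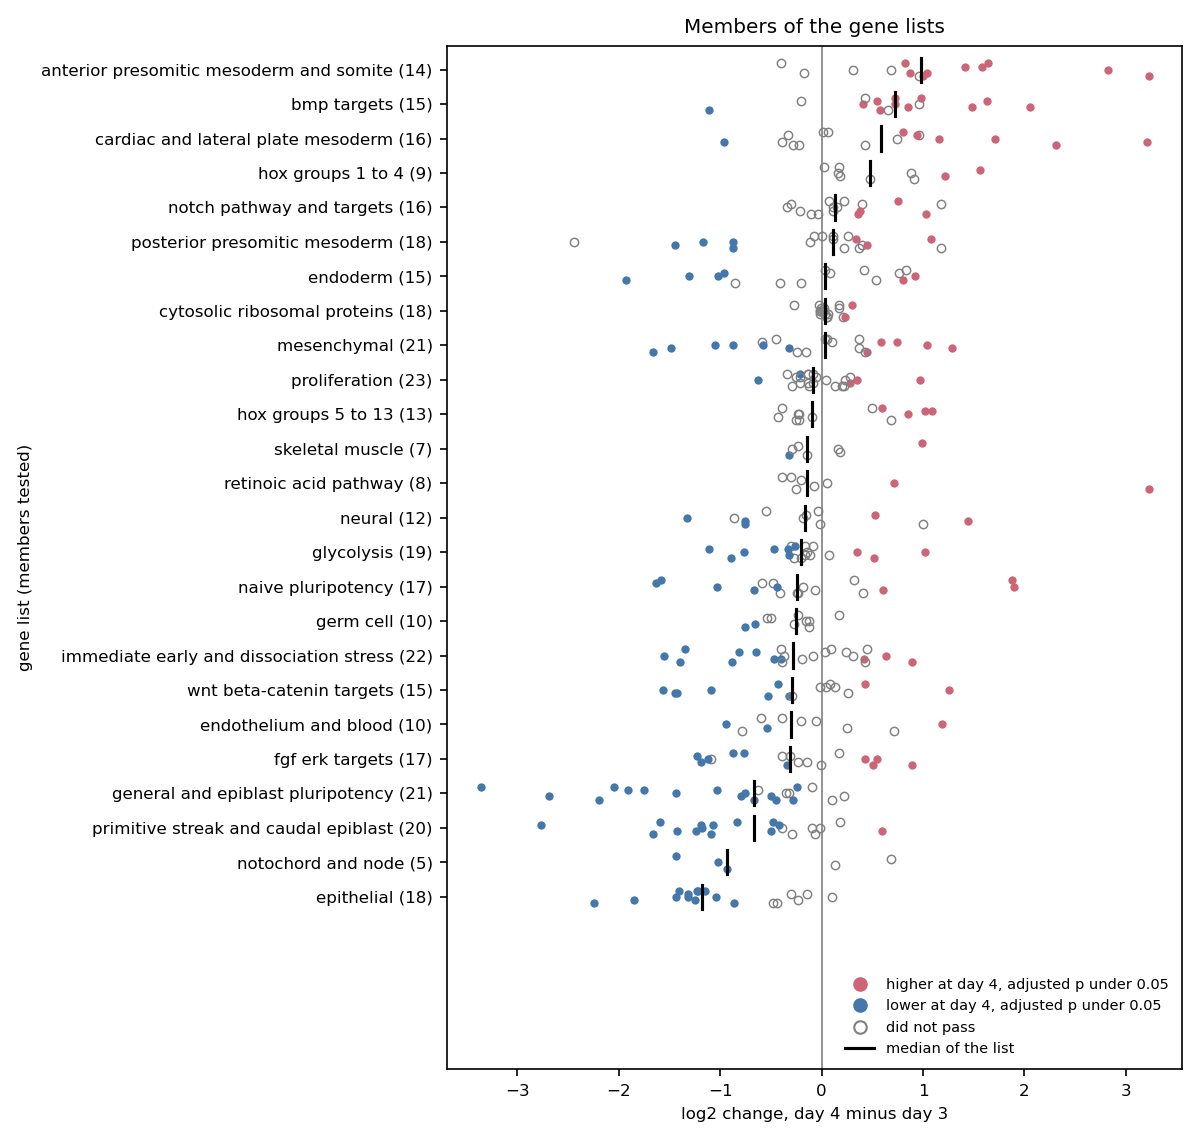
Log2 change (day 4 minus day 3) of each tested member of the 25 gene lists, sorted by the list's median (black bar), with members past adjusted p of 0.05 in red (higher at day 4) or blue (lower) and the others as open circles. Medians run from -1.18 for epithelial genes to 0.98 for anterior presomitic and somite genes.

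The rule fixed in advance ranked falls by the fitted log2 change, which for genes under the filter level at day 4 has only a bound. By the bounds the order differs, as L1td1 (10.3-fold) and Nefl and Nkx1-2 (6.82-fold and 6.81-fold) fell beyond the bound of Prmt8. The rule named Prmt8, an arginine methyltransferase, which fell at least 5.66-fold from 76.2 ± 6.27, Nptx2, a neuronal pentraxin, which fell at least 11.9-fold from 174 ± 11.7, and Lce1h, a cornified envelope gene, which fell at least 6.33-fold from 85.2 ± 0.90. The probe set of Lce1h carries a suffix for probes shared with other transcripts. L1td1, Nkx1-2 and Lefty1 were also among the 10 and are given above. Nefl, a neurofilament gene, fell by 2.77 ± 0.14 from 423 ± 36.0 to 62.3 ± 8.79 (adjusted p = 4.68e-06). Mfsd2a, a lipid transporter, fell at least 5.45-fold and the fatty acid receptor Cd36 at least 3.46-fold (adjusted p = 0.00765 and 0.00109). Shtn1 fell at least 2.60-fold (adjusted p = 0.0382), a call lost without any 1 of the day 3 replicates or day 4 replicate 2 (adjusted p up to 0.118).

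The 10 rises were ranked in the same way, by fitted changes that for 9 of them have only a bound, and Id2 (4.15-fold), given above, rose beyond several of these bounds. Aldh1a2, Meox1 and Tnni1 were among the 10. Mgam, a maltase-glucoamylase, rose at least 6.73-fold to 91.4 ± 15.9, Ppp1r3c, a glycogen-targeting phosphatase subunit, at least 6.30-fold to 98.4 ± 10.5, and the zinc finger gene Zc3h6 at least 5.73-fold to 77.4 ± 8.06 (adjusted p = 3.32e-05, 0.00186 and 0.000197). Pnliprp2, a lipase-related gene, rose at least 5.46-fold to 83.1 ± 11.9, Amer3 at least 3.20-fold and Proca1 at least 2.61-fold (adjusted p = 0.00547, 0.0136 and 0.00793). Kcnq3, a potassium channel gene, rose at least 2.82-fold to 47.2 ± 30.1 (adjusted p = 0.0187), a call lost without day 3 replicate 1 or 2 or day 4 replicate 2 (adjusted p up to 0.0736).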

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

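The alternatives below were planned before the data were examined. The count of changed genes, 2729 (1411 higher, 1318 lower), was 1796 with the mean over a gene's probe sets, 865 of them higher, and 4312 with array quality weights (2163 higher, 2149 lower). With every probe set tested on its own, 4795 probe sets changed (2693 higher, 2102 lower), a count of probe sets and not of genes. Leaving out 1 array gave 1582 to 3530 changed genes, 866 to 1750 of them higher and 716 to 1780 lower. Of the 2729 genes, 2604 remained without day 4 replicate 1, 1761 without day 3 replicate 2 and 1555 without day 3 replicate 3. With quantile normalization 2575 remained, and with the mean of probe sets 1515. The share of higher genes among those changed was 51.7%, and 46.1% with arrays centred on their medians, and these scalings moved the median of all genes by under 0.1. Same-numbered replicates did not deviate together (correlations 0.067, 0.011 and -0.001). Whether the numbers pair the samples is not known, as the labels do not say what was repeated. With a replicate block 2884 genes changed. Of the list calls, the block ended only that of the Wnt list (adjusted p = 0.0609). Among named genes, Tfap2c and Rpl11 passed with it (adjusted p = 0.0385 and 0.0185), and Actc1 and Tex19.1 did not (0.0655 and 0.0675).

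The general pluripotency, streak, anterior presomitic, BMP and epithelial lists kept their direction and call under all alternatives, with leave-one-out adjusted p of 1.37e-10 to 2.01e-09, 9.22e-08 to 2.13e-06, 3.15e-06 to 5.49e-05, 4.54e-07 to 5.32e-06 and 1.00e-10 to 6.58e-09. The other 5 calls were lost in places. With an estimated correlation, adjusted p was 0.304 for Wnt targets, 0.308 for Hox groups 1 to 4, 0.221 for the cardiac list, 0.304 for the notochord list and 0.377 for glycolysis. The estimate was below the preset 0.01 for the cardiac list (-0.036). It was also below for the general pluripotency (-0.019) and streak (-0.022) lists, whose adjusted p rose to 0.0314. For these lists the rise therefore does not measure correlation between members. For Wnt targets, Hox groups 1 to 4, the notochord list and glycolysis the estimate was higher (0.046, 0.151, 0.161 and 0.221). Wnt targets were at 0.0505 with quantile normalization, 0.0718 without probe sets of the suffixes _x_at, _s_at and _a_at (suffixed probe sets) and 0.0726 without trend. The cardiac list was at 0.0514 with the stricter filter, 0.091 with the mean of probe sets and 0.0551 without trend. The notochord list was at 0.0713 without trend and 0.0616 with weights, and glycolysis at 0.27 without suffixed probe sets, 0.0726 without trend and 0.0616 with weights. Leave-one-out adjusted p was 0.0252 to 0.0792 for Wnt targets, 0.0152 to 0.0535 for the cardiac list and 0.0308 to 0.077 for the notochord list. Notch passed without a filter (0.0396). Under fry, Notch (0.0123), FGF (0.00216), Hox groups 5 to 13 (0.000782), mesenchymal (0.0206), germ cell (0.00396) and stress (0.00176) also passed. Fry tests a list against no change and camera tests it against the other genes, so these passes do not compare with the camera calls. The mesenchymal list passed fry as higher, although its mean change was -0.09.

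Lists without a call changed direction in places. Posterior presomitic genes leaned lower with the stricter filter (0.841), the mean of probe sets (0.724), weights (0.974) and fry (0.431), and ran from 0.797 to 0.995 in leave-one-out. Mesenchymal genes leaned lower with the mean of probe sets (0.814; leave-one-out 0.843 to 0.967) and endoderm higher with the stricter filter (0.299; leave-one-out 0.718 to 0.939). Proliferation leaned higher with quantile normalization (0.974) and without suffixed probe sets (0.981), and ribosomal genes leaned lower without the latter (0.981). Skeletal muscle ran from 0.734 to 0.939 in leave-one-out. Among named genes, the mean of probe sets turned Hoxb4 (-0.056) and Sparc (-0.19), and leaving out suffixed probe sets turned Pfkl (0.49, limma adjusted p = 0.0422) and Rps24 (-0.31). Leave-one-out changes of Tbx6 ran from -0.30 to 0.026 and of Dll1 from -0.037 to 0.21. Beside leave-one-out, named genes kept their direction but lost their call in 46 gene and setting pairs and gained one in 7, and Sparc also lost its call where it turned. The cause of these losses and turns was not tested. Signal limits the dim genes: with no detection calls, folds from under 13.5 are bounds.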

Other observations

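Further gene families, picked after the gene tables had been seen and because members had changed, are given as counts. No shift is claimed for them, because they were picked in this way. At the preset correlation used for the lists, Bmp and Gdf ligands (camera adjusted p = 0.148) and semaphorins and plexins (0.301) did not pass. The other families tested passed, from 0.00109 for Wnt ligands to 0.037 for Meis and Pbx genes, but the choice of families makes these passes no evidence. With an estimated correlation none of the 11 families passed (camera adjusted p from 0.136 to 0.636). Of all 12285 genes tested, 2729 changed. The tests below of 5′ signal, of the day axis, of naive pluripotency genes and of other presomitic genes were likewise chosen after the result was seen. Of 15 tested Wnt ligands, 6 were lower and 0 higher at day 4 (7 and 0 without day 4 replicate 1). Beside Wnt3a they included Wnt6, which fell from 380 ± 19.6 to 91.2 ± 11.8, and Wnt4, from 139 ± 24.1 to 34.7 ± 8.60. Chaperones and cochaperones were lower in 15 of 62 and higher in 3 (20 and 3 without that array), with the copies Hspa1a and Hspa1b counted apart. Hspb1 fell by 1.24 ± 0.13, and Hspa5, the chaperone of the endoplasmic reticulum, by 0.38 ± 0.07 from 6260 ± 135. Both tested metallothioneins fell, Mt1 by 1.39 ± 0.15 and Mt2 by 1.51 ± 0.16. Proteasome subunits were lower in 11 of 47 and higher in 1 (15 and 2), and mitochondrial ribosomal proteins lower in 14 of 76 and higher in 3 (24 and 4). Synaptotagmins, stathmins and neurofilaments were lower in 5 of 14 and higher in 0 (7 and 1), Fgf ligands lower in 3 of 12 (3 and 0) and keratins lower in 3 of 19 (3 and 0). Zfp zinc finger genes were higher in 36 of 299 and lower in 12 (48 and 16), Meis and Pbx genes higher in 2 of 5 (2 and 0), Bmp and Gdf ligands higher in 3 of 11 and lower in 1 (4 and 1), and semaphorins and plexins higher in 5 of 24 and lower in 1 (4 and 1).

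Among abundant genes, picked after their values were seen, Clu, which encodes clusterin, rose from 617 ± 52.7 to 2790 ± 46.8. Txnip, an inhibitor of thioredoxin and glucose uptake, rose from 341 ± 37.2 to 1652 ± 142. Klf10 rose from 164 ± 19.7 to 728 ± 53.1 and Prdm6 from 176 ± 19.0 to 887 ± 56.7. Igfbp3, which binds insulin-like growth factors, fell from 1746 ± 61.1 to 359 ± 44.1, and Ckb, a creatine kinase, from 903 ± 60.6 to 144 ± 21.6. All 6 had limma adjusted p of at most 8.40e-06. Of 4750 tested probe sets with no single gene name, 761 changed.

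The 2729 changed genes can be set beside other groupings of the arrays. The real split was the only 1 of the 10 splits of the 6 arrays into 3 and 3 with as many genes, and the highest of the other 9 gave 0. With 10 splits the share cannot fall under 0.05. Each of the other 9 also mixed the days in both groups, where a difference between days adds to the spread within groups. Their counts of 0 therefore cannot decide how many of the calls are due to chance.

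Day 4 replicate 1 lay farther from the other day 4 arrays than these did from each other, by 1.93 times in median absolute log2 difference. A scaling difference is argued against, since the ratio was 1.95 after quantile normalization. A mislabelled day is argued against too: on an axis from day 3 (0) to day 4 (1) built from the other arrays it lay at 0.821. The other day 4 arrays lay at 0.786 and 0.804, each on its own axis, which replicate 1 helped to build. Another stage stays open, as such an axis cannot show a difference off it. On the first and second principal components replicate 1 lay at 33.7 and 32.0. Day 4 replicates 2 and 3 lay at 25.4 and 25.0 on the first and at -16.6 and -20.4 on the second. The ratio of 3′ to 5′ Gapdh signal of 14.0, against at most 3.19 elsewhere, is consistent with loss of signal toward 5′ ends, as shortened RNA or cRNA may give, and the 5′ signals of both controls were lower on the other day 4 arrays too. Neither a biological difference of this culture nor the extraction, for which the labels name both Trizol and an RNeasy kit without assigning samples, was tested.

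The fall of epiblast pluripotency genes may reflect fewer ES cells carried over in the sort, or an untested change within the cells or in the share of epiblast-like cells. Carry-over would lower naive genes about as far as Pou5f1 (-1.91) if only the carried-over cells expressed them. The 7 naive genes with a day 3 signal above 100 had a median change of -0.24 with an SD of 1.11, with -0.24 for Zfp42 and -0.44 for Zscan10. Nanog (-1.63) and, under that signal, Fbxo15 (-1.58) fell nearly as far as Pou5f1, while Socs3 rose by 1.88 and Tbx3 by 0.60. Carry-over alone thus does not set the signals of these naive genes, so their median cannot decide, and carry-over stays open. Signal loss in day 4 replicate 1 alone is argued against, as the list kept its shift without that array (camera adjusted p = 2.01e-09). The 5′ control signals were lower on the other day 4 arrays too, which leaving out replicate 1 cannot address.

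Msgn1 fell in cells sorted on its own reporter. Fewer presomitic cells in the gate would lower the other presomitic genes about as far (-1.17) if only those cells expressed them. The 14 others with a day 3 signal above 100 had a median change of 0.057 (SD 0.90). Dkk1 (-1.45) fell further than Msgn1, and Cdh11 (-0.88) and Dusp4 (-0.87) fell less far. Cited1, picked after its value was seen, was at -2.44 ± 0.88 without passing (limma adjusted p = 0.0766), and Rspo3 rose by 1.08. The members thus went both ways, and the number of such cells alone does not set their signals. Whether these genes were confined to such cells was not tested, so their median cannot decide, and fewer such cells stays open. Noise of a dim probe set that rests on 1 array would be expected to end the call when that array is left out. The highest limma adjusted p in those 6 fits was 0.0406, so no single array made the call. A fault shared by the arrays of a day would survive these fits, and Msgn1 had no other probe set. A Venus protein that outlasts the Msgn1 transcript may also give this pattern, which was not tested, since no probe set is named for the reporter, and a true fall with the day stays open as well.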
